A study of Mus musculus with 6 samples.

How the data were processed

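Gene expression was measured on an Illumina mouse bead array with 1 probe value per array, in DCs sorted from peripheral lymph nodes of antibiotic-treated and untreated mice, 3 arrays per group. Groups and replicate numbers were taken from the sample labels. The labels call the arrays replicates but do not say that they come from separate animals or pools, so p-values measure the spread between these samples, which may be technical. The labels' protocols name RNA extraction with a kit, biotin labelling and sorting after staining, and the gate is not given in the sources used here.

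The authors deposited a table of probe intensity that was not background-corrected or normalized between arrays, per the file headers and as its values show, since array medians differed (84.7 to 89.2) and no value was below 0. The authors also deposited a detection p-value for each probe and array, per the file headers. A second deposited table held normalized intensity on a linear scale, with a near-identical distribution on all 6 arrays and 44.6% of values below 0, and how it was made is not given in the sources used here. The series' value table equalled that second table in all 154182 cells. Its scale is linear and not centred, with array medians of 1.1 to 1.2.

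The non-normalized intensity was corrected and normalized here with limma 3.58.1 in R 4.3.3. The neqc procedure inferred each array's background from the detection p-values, applied normexp background correction, added an offset of 16, quantile-normalized the arrays and took log2. Because of the offset and background, log2 fold changes of dim genes are understated. Quantile normalization forces equal distributions on all arrays, so a shift of all genes together would not be seen. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 7507 (29.2%) of 25697. Gene symbols came from the platform annotation. It gave 1 symbol to 23978 probes, several to 0 and none to 1719, and 0 symbols needed updating. For a gene with several kept probes (1001 genes) the probe with the highest mean over all 6 arrays stood for it, which left 6331 rows, 5901 named genes and 430 unnamed probes. Among genes taken by the naming rule, kept probes differed in sign for Rpl29, Edem2 and Acta2. No genome build is named in the sources used here, and no coordinates are given.

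Antibiotics were compared with untreated arrays by limma's lmFit and eBayes, with 8.57 total degrees of freedom per gene, and p-values were adjusted by Benjamini-Hochberg over all 6331. The threshold was an adjusted p of 0.05. With 3 arrays against 3, an exact permutation test of a single value cannot give a p under 0.1. Fold changes are antibiotics minus untreated on the log2 scale, with limma's SE. Where a probe was detected on 0 arrays of a group, the fold is given as a bound: the mean of the detected group against the mean, per array, of the higher of the lowest signal among detected probes and the probe's own.

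Of 31 gene and marker lists (17 gene lists, 14 cell type marker lists), the 28 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28. Camera with an estimated correlation, fry and camera on ranks were run beside it. The gene lists were type I interferon-stimulated genes, interferon-gamma-induced genes, NF-kB target genes, cytokines and chemokines, mature and migratory DC genes, T cell costimulation and coinhibition, MHC class II presentation, MHC class I presentation, pattern recognition receptors and adaptors, microbial metabolite sensing, cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, unfolded protein response, immediate early and heat shock genes, and ribosomal proteins. The marker lists were DC core, cDC1, cDC2, Langerhans cell, plasmacytoid DC, B cell, plasma cell, T cell, NK cell, macrophage and monocyte, neutrophil, basophil and mast cell, erythroid and platelet, and lymph node stroma and endothelium. Lists were written from general knowledge of these pathways, and some genes stand in several lists. The 5 lists past the threshold share 0 genes with each other. Genes of different lists can still vary together, so these are not 5 independent results.

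The lists, the test, the threshold, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes per direction with the largest change among those past the threshold with no overlap between groups. Where fewer passed, it filled up to 10 per direction with the smallest unadjusted p among genes with an absolute log2 fold change of at least 0.58 (1.5-fold) and no overlap, given as values that did not pass. It added up to 4 members per list by smallest p, and identity genes, of which Itgax, Flt3, Zbtb46, H2-Ab1, Cd3e, Ncr1, Lyz2, Siglech and Ifnb1 are reported and 1 is not reported here. Named members outside the rule are those that passed over their list alone and the 2 interferon-stimulated genes that were higher. Vcam1 and Fcgr4, as abundant macrophage and monocyte markers, Ly6c1 and Batf3 are also outside it. So are Cd80, Cd86, Cd83 and Fscn1 of the mature and migratory DC list and Xcr1, Irf8 and Ppt1 of the cDC1 list. All of these were chosen after their values were seen.

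The procedure was tested on 20 simulated data sets of the comparison with 200 of 6331 genes changed. At an adjusted p of 0.05 it recovered 67.5% of genes changed by 1 on the log2 scale and 95.7% of those changed by 2, with 4.69% false calls. A list of 27 genes lowered by 0.3 was found by camera with the preset correlation in 20 of 20 data sets and with an estimated correlation in 2, and 0% of 30 unchanged lists per data set were called with the preset correlation. Genes were simulated as independent, so this says nothing of lists whose genes vary together.

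Alternatives changed the background correction, the normalization (including the authors' normalized table), the filter on dim probes, the choice among probes, the variance model, array weights, the replicate number as a block, the set test, and left out each array in turn.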

Results

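Dendritic cells (DCs), the antigen-presenting cells that prime T cells, were sorted by flow cytometry from the peripheral lymph nodes of mice that had received broad-spectrum antibiotics by oral gavage for 10 days and of untreated mice. The titles of the untreated samples read no treatment and name no gavage. If those mice had none, effects of gavage and of antibiotics cannot be told apart. Total RNA from each sort was labelled with biotin and hybridised to an Illumina mouse bead array, with 3 arrays per group and 6 in all. Between 6876 and 7674 of the 25697 probes were detected per array, the fewest on antibiotics replicate 1 and the most on untreated replicate 3. The arrays resembled each other closely, with correlations across the tested genes between 0.963 and 0.984. Antibiotics replicate 1 stood apart, at -25.3 on the first principal component where the other 5 arrays lay between 1.36 and 11.5. The number of arrays limits the precision of each value: the median SD between arrays of a group was 0.22 on the log2 scale.

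The comparison asked whether 10 days of antibiotics altered gene expression in lymph node DCs. Type I interferon-stimulated genes, the antiviral set that interferon alpha and beta switch on, were lower after antibiotics, with 25 of 27 measured members below the untreated level and a median log2 fold change of -0.30. Genes of MHC class I presentation, the route that displays peptides to CD8 T cells, were also lower, 17 of 18 at a median of -0.19. All 13 measured markers of cDC1, the conventional DC subset specialised in cross-presentation, were higher, at a median of 0.32. Without antibiotics replicate 2, 10 of the 13 were higher. These 3 lists passed camera with a preset correlation (adjusted p = 6.32e-10, 3.56e-04 and 2.89e-04) and did not with an estimated correlation (adjusted p = 0.162 for each). No single gene passed. Of 6331 genes and unnamed probes, 0 reached an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.214. At an unadjusted p under 0.05 there were 490, 216 higher and 274 lower after antibiotics, where 317 are expected by chance. A split of the 6 arrays that mixed both groups gave 499, so a count this high is not particular to the treatment. With median scaling 243 of 469 were higher. In 870 (13.7%) the 3 arrays of one group all lay on one side of the other 3, a share that chance alone puts at 10%.

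For each direction, 10 genes are given as values that did not pass. They had the smallest p in that direction among genes that differed by at least 1.5-fold without overlap between the groups. Lower after antibiotics were Fabp5, a fatty acid-binding protein, by a log2 fold change of -1.24 (SE 0.17), Cd1d1, which presents lipid antigens to natural killer T cells, by -1.32 (SE 0.23), and the interferon-induced gene Ifit3 by -1.21 (SE 0.18). Normalized Fabp5 was 6.59 ± 0.22 (SD, n = 3) after antibiotics and 7.82 ± 0.19 (SD, n = 3) without, in log2 units. The tubulin gene Tubb2b lay at -0.99 (-0.51 and -1.15 with its other probes), the guanylate-binding protein Gbp3 at -0.90, the plakophilin Pkp3 at -0.85 and the mitochondrial ribosomal protein Mrps27 at -0.77. A second probe for Gbp3 gave only -0.16. Kcnn1, Rgs9bp and Sertad3 were detected on all 3 untreated arrays and on 0 antibiotics arrays, so that their levels were at least 1.31-fold, 1.39-fold and 1.29-fold lower, each with a limma adjusted p of 0.214. These bounds set the untreated mean against the lowest signal of detected probes. Higher after antibiotics were Ephx1, the microsomal epoxide hydrolase, at 0.94 (SE 0.15), the dipeptidase gene Dpep2 at 0.89 (SE 0.15), the hexokinase gene Hk3 at 1.02 (SE 0.18) and Fblim1 at 1.17 (SE 0.20). Msc showed 1.36 (SE 0.30), and the tetraspanin gene Cd9 and Marchf1, the ubiquitin ligase that removes MHC class II from the cell surface, showed 0.73 and 0.70. Ncaph2, Nudt6 and Mfsd3 lay between 0.72 and 0.89, and other probes for Ncaph2 gave 0.57 and 0.075. The adjusted p of these 20 genes ran from 0.214 to 0.344.

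**Figure D1:**
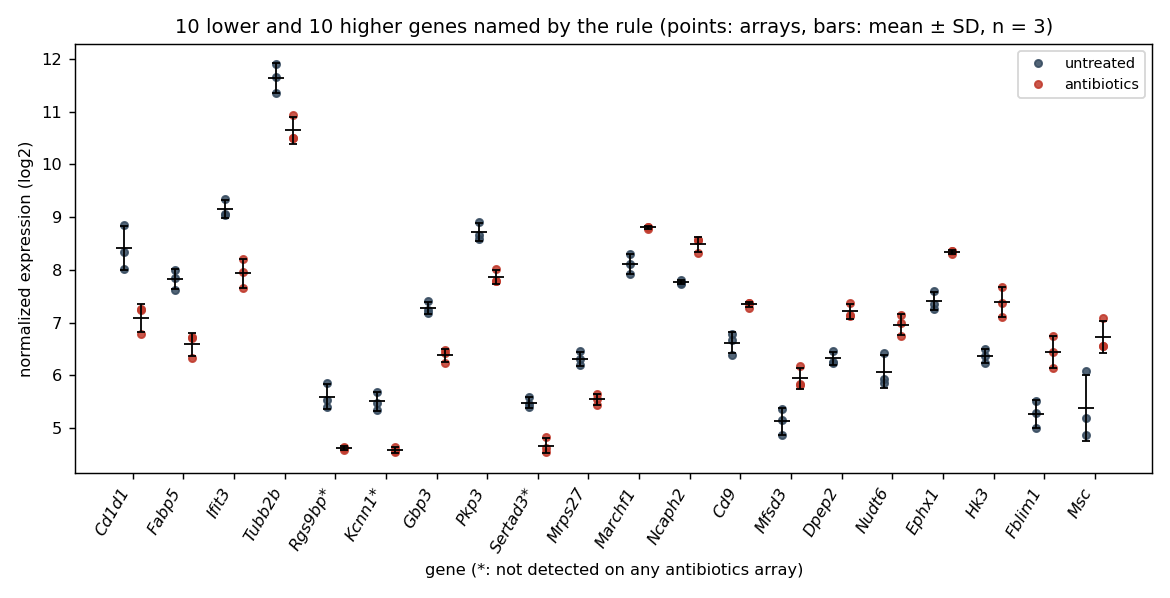
Normalized log2 expression (vertical axis) of 20 genes, with 3 untreated and 3 antibiotics arrays as points and mean ± SD as bars. They are, per direction, the 10 with the smallest unadjusted p among genes with at least a 1.5-fold difference and no overlap between groups. Fabp5 had means of 7.82 without and 6.59 after antibiotics, and none of the 20 passed the adjusted threshold.

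Type I interferon-stimulated genes fell as a group (camera adjusted p = 6.32e-10 with a preset correlation between genes). The adjusted p was 0.162 with an estimated correlation, so this call, like that of every other list below, did not hold there. In the simulations of independent genes that version found the lowered list in only 2 of 20 data sets, so it had little power there. The simulations do not cover lists whose genes vary together. For such lists a preset correlation of 0.01 may be too low, so the miss cannot be set aside. The estimated correlation was 0.10 for this list, -0.010 for MHC class I presentation and 0.027 for cDC1. It was 0.19 for mature and migratory DC genes and 0.22 for ribosomal proteins. The list's mean log2 level was 7.13 ± 0.055 (SD, n = 3) after antibiotics and 7.52 ± 0.14 (SD, n = 3) without, and all 3 antibiotics arrays lay below the 3 untreated ones. Of the 27 members, 8 were lower at an unadjusted p under 0.05 (13 without untreated replicate 3) and 0 were higher. In 12 members the groups did not overlap, and all 12 were lower. Over all genes this share was 13.7%, where chance gives 10% counting both directions. Members of the list vary together on the same arrays, so the 12 are not independent. Adjusted over the list alone, 7 passed and over all genes 0. The 7 were Ifit3, Ifi27l2a, Oas1g, Rsad2, Oasl2, Cmpk2 and Irf7, which include antiviral effectors such as Rsad2 (viperin) and the oligoadenylate synthetase Oas1g, and Irf7, the transcription factor that amplifies interferon production. Rsad2 stood at -1.10 (SE 0.28), Ifi27l2a at -0.91 (SE 0.18), Oas1g at -0.79 (SE 0.17) and Irf7 at -0.54 (SE 0.15). The 2 members above the untreated level were Samd9l at 0.086 and Tor3a at 0.10, named after their values were seen. The count of 7 depended on single arrays, and was 3 without antibiotics replicate 1, 1 without untreated replicate 1, 2 without untreated replicate 2 and 11 without untreated replicate 3. The size of the shift depended on the processing, with a list median of -0.15 without background correction, -0.19 with normexp at an offset of 50 and -0.13 without the filter on dim probes, which adds dim members. Interferon beta itself, Ifnb1, was detected on 0 arrays.

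Interferon-gamma-induced genes lay on both sides of the untreated level. Of 15 measured, 10 were lower and 5 higher, with a median of -0.11 that did not pass (camera adjusted p = 0.111). The list's level on all 3 antibiotics arrays still lay below all 3 untreated ones, at 8.58 ± 0.011 against 8.72 ± 0.033 (SD, n = 3). Adjusted over the list alone, 2 passed. Gbp3 was lower, and Cxcl9, a chemokine that draws activated T cells, was higher at 0.87 (SE 0.20). Cd274, which encodes the inhibitory ligand PD-L1, and Gbp2 stood at -0.63 and -0.43 and did not pass. Fry, which tests whether the members of 1 list move on balance one way, gave this list an adjusted p of 0.0232, without comparing it with other genes.

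**Figure D2:**
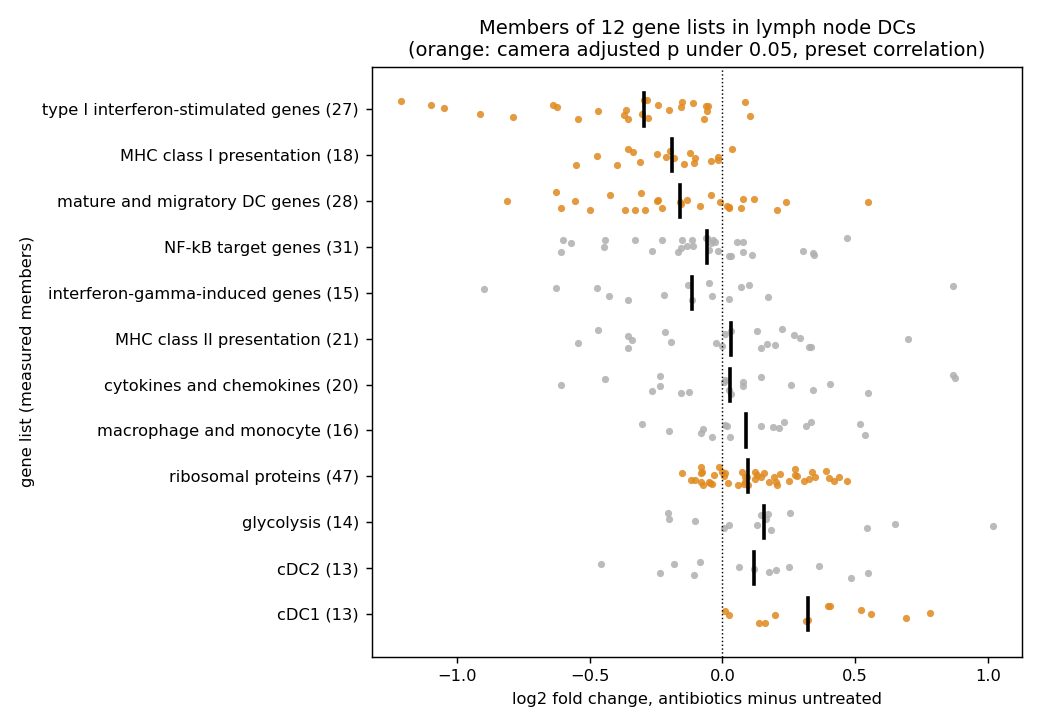
The log2 fold change (horizontal axis, antibiotics minus untreated) of each measured member of 12 gene lists (vertical axis, number of members in parentheses), with 1 point per gene and a black bar at the list's median. Medians ran from -0.30 for type I interferon-stimulated genes to 0.32 for cDC1 markers, and orange marks the lists past a camera adjusted p of 0.05 with the preset correlation.

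Genes of mature and migratory DCs, which DCs switch on when they leave tissue for the lymph node, were lower as a group, with 19 of 28 below the untreated level and a median of -0.16 (camera adjusted p = 0.0063, and adjusted p = 0.699 with an estimated correlation). Adjusted over the list alone, 2 passed, Stat4 at -0.81 (SE 0.18) and the costimulatory receptor gene Cd40 at -0.61 (SE 0.15), and over all genes 0. Stat4 was detected on 1 of 3 antibiotics arrays. Both other probes for Cd40 gave -0.33. Bcl2l14 at -0.56 and the chemokine receptor gene Ccr7 at -0.29 did not pass, nor did Ccl17 at 0.55. The groups overlapped in the list's level, 9.29 ± 0.093 after antibiotics against 9.47 ± 0.11 without (SD, n = 3). The call was lost without antibiotics replicate 2 (adjusted p = 0.180, median -0.13) and without untreated replicate 2 (adjusted p = 0.0992, median -0.14). The median was -0.31 without untreated replicate 3, and the count of 2 fell to 0 or 1 without any single array. NF-kB target genes, the classic inflammatory programme, did not pass, with 21 of 31 lower and a median of -0.059 (camera adjusted p = 0.182). They passed without antibiotics replicate 3 (adjusted p = 0.0367, median -0.12) or without untreated replicate 3 (adjusted p = 0.0147, median -0.11), and the median was 0.0025 without antibiotics replicate 2 and -0.015 without untreated replicate 1. Among them Bcl3 stood at -0.60, Traf1 at -0.57 and Tnfaip2 at 0.47 (0.060 and 0.32 with its other probes), all short of the threshold over the list alone. Cytokines and chemokines did not pass either, with 13 of 20 higher and a median of 0.029 (camera adjusted p = 0.496). That median ran from -0.0057 to 0.11 over the 20 alternatives. Cxcl9 passed over the list alone, and Tnfsf13b (BAFF, a B cell survival factor) at 0.87 and Ebi3 at 0.41 did not. In the list of T cell costimulation and coinhibition, 6 of 10 members were higher and 4 lower (median 0.093, camera adjusted p = 0.937). Cd40 passed over the list alone, and the inhibitory receptor genes Btla at 0.49 and Havcr2 at 0.36 did not.

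MHC class I presentation genes fell as a group (camera adjusted p = 3.56e-04, and adjusted p = 0.162 with an estimated correlation), and the list's level on all 3 antibiotics arrays lay below all 3 untreated ones, at 8.69 ± 0.042 against 8.90 ± 0.064 (SD, n = 3). No member passed, with 0 over the list alone (1 without antibiotics replicate 1) and 0 over all genes. Without the filter on dim probes the list's median was -0.11. H2-Q8 stood at -0.55 (SE 0.14), H2-D1 at -0.40 (SE 0.15), Nlrc5, the transactivator of MHC class I genes, at -0.47 (SE 0.18) and H2-Q7 at -0.31 (SE 0.15). The H2-D1, H2-Q7 and H2-Q8 genes are close relatives, and their probes can share signal. MHC class II presentation did not pass, with 12 of 21 higher, 8 lower and 1 at 0 (median 0.033, camera adjusted p = 0.948). Marchf1 passed over the list alone, while Cd63 at -0.54, Ifi30 at -0.35 and H2-DMb2 at -0.47 did not. H2-Ab1, among the brightest probes of the array, showed 0 after quantile normalization, which gives equal values to top-ranked probes, and its other probes lay between -0.41 and -0.020.

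**Figure D3:**
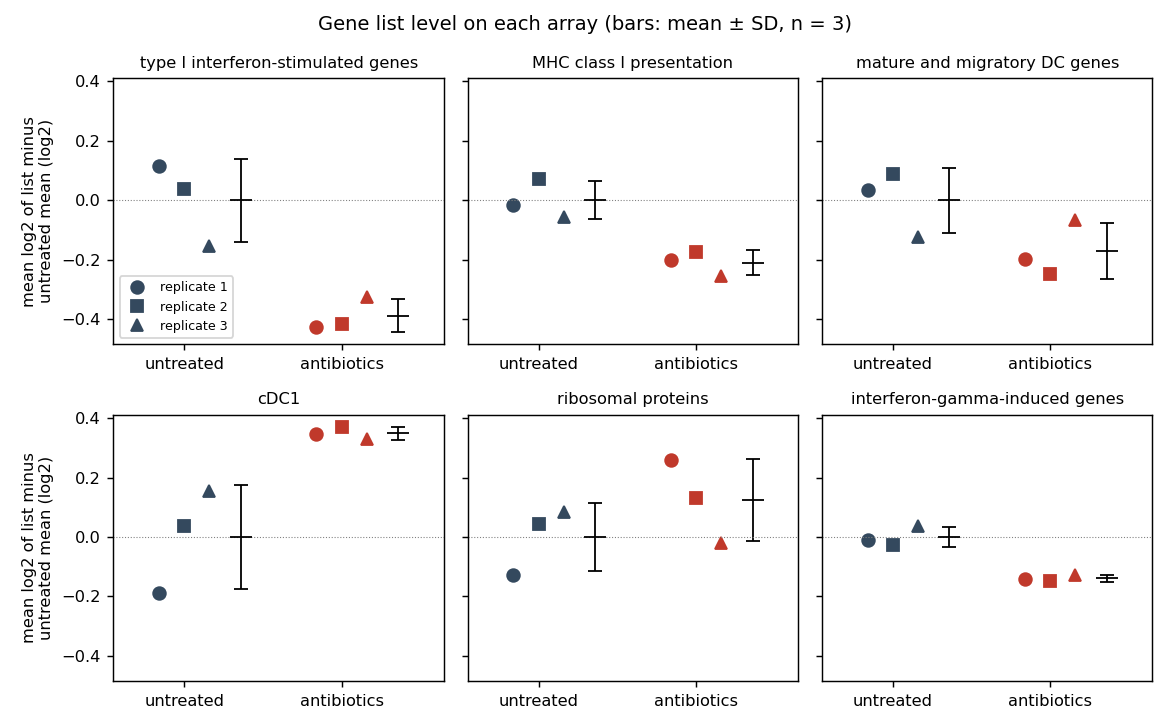
Mean log2 level of 6 gene lists on each array, as the difference from the untreated mean in log2 units (vertical axis), for untreated and antibiotics arrays (horizontal axis), with symbols for replicates and bars for mean ± SD of 3 arrays. The antibiotics arrays lay between -0.42 and -0.32 for type I interferon-stimulated genes and between 0.33 and 0.37 for cDC1, apart from the untreated arrays in both.

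The cDC1 markers rose as a group (camera adjusted p = 2.89e-04, and adjusted p = 0.162 with an estimated correlation), at 7.38 ± 0.021 after antibiotics and 7.03 ± 0.17 without (SD, n = 3). Adjusted over the list alone 1 of 13 passed, the adhesion molecule gene Cadm1 at 0.78 (SE 0.19), and over all genes 0. Plpp1 at 0.69, Rab7b at 0.56 and Tlr11, a receptor for microbial profilin, at 0.52 did not pass. The subset genes Xcr1 and Irf8 stood at 0.32 (SE 0.27) and 0.16 (SE 0.14), and Batf3 and Ppt1 at 0.025 and 0.011. The single pass over the list alone was lost without antibiotics replicate 1 or 2 and without untreated replicate 1 or 2, and there were 2 without untreated replicate 3. Of the 13 members, 10 were higher without antibiotics replicate 2 and 11 without untreated replicate 1. The count was 12 without antibiotics replicate 1 or untreated replicate 2. The list's median was 0.15 without background correction, 0.19 with normexp at an offset of 50, 0.16 without the filter on dim probes and 0.49 with the authors' normalized table. The other lists of DC subset and core markers did not pass. The cDC2 list had a median of 0.12 (8 of 13 higher, camera adjusted p = 0.480), with Esam at -0.46 and Cx3cr1 at 0.48. The Langerhans cell list had 0.14 (5 of 6 higher, camera adjusted p = 0.358), with Cd207 (langerin) at 0.74 (0.45 with its other probe). Plasmacytoid DC markers had -0.060 (6 of 10 lower, camera adjusted p = 0.480), with Atp1b1 at -0.57, Cox6a2 at -0.33 and Bst2, also an interferon-stimulated gene, at -0.36. Core DC genes had -0.079 (7 of 12 lower, camera adjusted p = 0.534), with Dpp4 at -0.37. Itgax (CD11c) at 0.15 and the DC transcription factor gene Zbtb46 at -0.13 were detected on all 6 arrays.

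Markers of other cells that a lymph node sort could hold did not pass as groups. Macrophage and monocyte markers had a median of 0.088 (11 of 16 higher, camera adjusted p = 0.267), with the lysozyme gene Lyz2 at 0.54 (0.14 with its other probe) and the macrophage receptor gene Adgre1 at 0.33. B cell markers had -0.082 (5 of 8 lower, camera adjusted p = 0.437). Within the B cell list Fcmr at -1.06 (SE 0.27), Chst3 at -0.72 (SE 0.22) and Cd22 at -0.79 (SE 0.25) passed when adjusted over the list alone, and Fcrla at 0.43 did not. Fcmr and Cd22 were dim, each detected on 2 of 3 antibiotics arrays, and the groups overlapped for Cd22. Over the alternatives Fcmr ran from -1.81 to -0.40 and Cd22 from -1.18 to -0.30. Plasma cell markers had 0.26 (3 of 5 higher, camera adjusted p = 0.258), and Txndc5 at 0.51 passed over the list alone. T cell markers had -0.018 (4 of 7 lower, camera adjusted p = 0.948), NK cell markers -0.038 (3 of 6 lower, camera adjusted p = 0.948) and lymph node stroma and endothelium 0.091 (3 of 5 higher, camera adjusted p = 0.948). The signal of the T cell gene Cd3e, the NK cell gene Ncr1 and the DC growth factor receptor gene Flt3 was detected on 0 arrays, and that of the plasmacytoid DC gene Siglech on 2. Neutrophil, basophil and mast cell, and erythroid and platelet markers had 4, 1 and 0 measured members and were not tested.

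Ribosomal protein genes passed with a small shift, 33 of 47 higher at a median of 0.096 (camera adjusted p = 0.0366, and adjusted p = 0.699 with an estimated correlation). Rpl12 stood at 0.42 and Rps15 at 0.35, and 0 members passed over the list alone or over all genes. The groups overlapped, at 10.56 ± 0.14 after antibiotics and 10.43 ± 0.11 without (SD, n = 3, log2). The call was lost without antibiotics replicate 1 (adjusted p = 0.405), antibiotics replicate 2 (0.180) or untreated replicate 1 (0.675). The median was 0.058, 0.096 and 0.037 in these 3 fits, and 0.16 without untreated replicate 2. Glycolysis genes did not pass, with 11 of 14 higher and a median of 0.16 (camera adjusted p = 0.0741). Hk3 passed over the list alone, and Hk2 at 0.54 and Pfkm at 0.65 (0.13 with its other probe) did not. Without antibiotics replicate 1 the glycolysis list passed (adjusted p = 0.0234, median 0.12), and without each of the other arrays its adjusted p lay between 0.0797 and 0.374.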

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

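The counts of list members without each array were chosen only after the data were seen. The count at an adjusted p of 0.05 was 0 under all 20 alternatives, with the smallest adjusted p between 0.0623 (the authors' normalized table) and 0.677. At a threshold of 0.1 it was 0 with the settings reported, while the smallest adjusted p lay under 0.1 with the authors' normalized table, the equal series values and array weights (0.0940). At an unadjusted p under 0.05 the count stayed within 1.5 times of 490, except 1094 of 18312 without a filter on dim probes, where more probes were tested. Leaving out each array gave 341 to 549. Higher genes made up 44.1% of the 490, 51.8% with median scaling, 52.9% without the filter and, with array weights, 345 of 690. The calls of type I interferon-stimulated genes, MHC class I presentation and cDC1 held in all 20 (highest adjusted p 7.75e-07, 0.0108 and 0.00972) and on ranks, but not when the correlation was estimated (0.162 for each) or under fry (0.0670, 0.0670 and 0.106), which does not compare a list with other genes. Mature and migratory DC genes held in 18 of 20 and on ranks (0.0258). Their adjusted p was 1.80e-04 to 0.180 over the left-out arrays, 0.699 with an estimated correlation and 0.500 under fry. Ribosomal proteins held in 12 of 20 and on ranks (0.0301). They missed with median scaling (0.130), the authors' normalized table and the equal series values (0.0981), array weights (0.434), an estimated correlation (0.699) and fry (0.500), and ran from 0.00119 to 0.675 over the left-out arrays. NF-kB target genes ran from 0.0147 to 0.739 over the left-out arrays. Interferon-gamma-induced genes passed with median scaling (0.0371), glycolysis with cyclic loess (0.0452), every probe as its own row (0.0205) and the mean over probes (0.0487), and the Langerhans cell list with every probe as its own row (0.0490). Beyond the counts of genes and samples, the cause of these changes was not tested. Among named genes, signs changed when an array was left out for Cd6 (-1.15 to 0.067), Klri2 (-0.42 to 0.023), Prf1 (-0.047 to 0.65) and Des (-0.091 to 0.22), and for Des with array weights (-0.031), none of them past the threshold. Dim genes are limited by signal over background, since 29.2% of probes were kept.

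Same-numbered arrays of the 2 groups share only a number. Their deviations from the group means correlated at -0.046, -0.060 and -0.15, and 0 of 3 correlated best with its own number. With the replicate number as a block, 0 genes passed the adjusted threshold and 417 an unadjusted p of 0.05, and the ribosomal protein list stood at 0.0545. It changed no other call. A fit with the slide as a block was not run, since the sources used here name no slide.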

Other observations

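The tests of left-out arrays and of macrophage, plasmacytoid DC and Langerhans cell markers were chosen only after the values were seen. Among lists not described so far, pattern recognition receptors and adaptors had 14 of 26 members lower (median -0.058, camera adjusted p = 0.480). The receptor gene Tlr1 stood at -0.58 (SE 0.16) and the sensor gene Dhx58 at -0.28, and 0 members passed over the list alone. In microbial metabolite sensing, 7 of 13 were higher and 6 lower (median 0.068, mean -0.0038, camera adjusted p = 0.986). Ffar2, a receptor for short-chain fatty acids made by gut bacteria, passed over the list alone at -0.61 (SE 0.13), with 9.48 ± 0.067 after antibiotics and 10.09 ± 0.052 without (SD, n = 3, log2), and the liver X receptor gene Nr1h3 at 0.18 did not.

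Oxidative phosphorylation genes had 34 of 50 higher (median 0.040, camera adjusted p = 0.480), with the complex I gene Ndufs8 at 0.56. Over the 20 alternatives the list's median ran from -0.014 to 0.13. Cholesterol synthesis had 7 of 13 higher (median 0.045, camera adjusted p = 0.937), with Msmo1 at 0.32. Its median ran from -0.043 to 0.16 over the 20 alternatives. The unfolded protein response had 10 of 15 lower (median -0.099, camera adjusted p = 0.480), with Pdia4 at -0.43. Immediate early and heat shock genes had 13 of 27 higher (median -0.0041, camera adjusted p = 0.937), with the transcription factor gene Egr2 at 0.80 (SE 0.23), and cell cycle genes had 10 of 20 higher (median 0.0038, camera adjusted p = 0.986), with Rrm2 at -0.47. None of these 5 examples passed over its list alone. The direction camera gave was opposite to the median's for immediate early and heat shock, cell cycle, NK cell and stroma lists, none of which passed. Over all probes, 44 were detected on all 3 untreated arrays and 0 antibiotics arrays, and 9 the other way round. The antibiotics arrays detected 6876, 7370 and 7299 probes and the untreated arrays 7428, 7422 and 7674.

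The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 gave 0 genes at an adjusted p of 0.05, as the real split did, and the highest other was 0. In 2 of 10 at least 490 genes reached an unadjusted p under 0.05, the highest other being 499, and in 2 of 10 at least 5 lists passed, the highest other being 7. So the preset correlation also passes lists in groupings that mix treated and untreated arrays. The smallest camera p belonged to the real split alone (1 of 10) for type I interferon-stimulated genes (2.26e-11, next 1.20e-05), MHC class I presentation (3.81e-05, next 0.00581) and cDC1 (2.07e-05, next 0.00366). For mature and migratory DC genes it was as small in 2 of 10 (9.00e-04, smallest other 5.79e-06), and for ribosomal proteins in 4 of 10 (0.00654, smallest other 6.15e-06). The list medians stood less far apart. For type I interferon-stimulated genes the largest absolute median in another split was 0.28, against -0.30 in the real one. It was 0.27 for cDC1 (real 0.32) and 0.12 for MHC class I presentation (real -0.19). Mature and migratory DC genes reached 0.22 (real -0.16) and ribosomal proteins 0.14 (real 0.096).

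The lower interferon-stimulated genes may reflect less tonic interferon signalling in DCs after antibiotics, a hypothesis that no measurement of interferon here tests. A single array as the cause is argued against, since the list median stayed at -0.27 or lower without each array and its adjusted p at 7.75e-07 or lower. Dim probes are argued against too, since the 14 brighter members had a median of -0.36, 2 of them above 0. Fewer macrophages or monocytes would lower their markers, of which 11 of 16 were higher and 5 lower. Their median was 0.088, which was 0.38 above the interferon list (permutation p = 9.00e-05), and 0.0053 to 0.20 over the 20 alternatives. Of the 5 most abundant, Lyz1, Lyz2, Axl and Vcam1 stood at 0.32, 0.54, 0.15 and 0.21 and Fcgr4 at -0.074 (SE 0.30). Axl is also on the Langerhans cell list, and Ly6c1 stood at -0.30 (SE 0.25). The permutation, like those below, shuffled genes between lists as if independent, so its p does not measure the spread between arrays. The markers as a set did not fall, but fewer monocytes alone are not excluded. Fewer plasmacytoid DCs, which carry high interferon-stimulated transcripts, cannot be told apart, since the 9 markers not shared with the list had a median of -0.014 but an SD of 0.28 (permutation p = 0.0327).

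The higher cDC1 markers may reflect a larger share of cDC1 cells in the sort, higher expression per cell, or both. A single array is argued against, since the median stayed at 0.24 or higher and the adjusted p at 0.00972 or lower without each array. If only cDC1 cells expressed the markers, a larger share would move them all by about one factor. That was not tested, and the understated changes of dim genes blur it. Of 13 members, 2 lay over 2 SE from the list's mean of 0.35, Cadm1 above and Batf3 below. Before the test was run, at most 2 was set as the outcome that a larger share would give. The count of 2 met that limit, at its edge. It does not decide between a larger share and higher expression. With SEs of 0.14 to 0.33 per gene this test has little power, and expression per cell was not measured.

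The lower mature and migratory DC genes, 19 of 28 members, may reflect fewer migratory cells or less maturation. The other 9 members were higher. Among list members not given above, Cd80 stood at 0.24 (SE 0.14) and Cd86 at 0.12 (SE 0.16). Cd83 lay at -0.041 and Fscn1 at -0.0072, so the list did not fall as a whole. Fewer Langerhans cells, a migratory type, would lower their markers, which had a median of 0.14 over 6 genes (permutation p = 0.0488 for the difference of medians). With 6 genes and an SD of 0.30 this cannot be told apart. Nor can the effect of single arrays, since the median stayed at -0.11 or lower without each array while the adjusted p reached 0.180.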
